A study of Homo sapiens with 458 samples.

How the data were processed

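HEK293T cells, a line derived from human embryonic kidney, were sorted singly into 96-well plates, and Smart-seq3xpress libraries were made from each cell, per the labels' protocols. Smart-seq3xpress is a plate-based, miniaturised method of single-cell RNA sequencing that primes on poly(A) tails. The deposited table held whole-number counts for 24624 genes in 458 cells, and each column matched the title of a single cell. No column of another sample was present. The submitters' processing notes name the genome build hg38 and the tools Picard, GATK, featureCounts 2.0.1 and Seurat 5.0.3, without their role or order. The aligner, the annotation and the cell filter are not given in the sources used here, nor is it stated whether the deposited counts are of reads or of molecular identifiers. Read counts that share a molecule would make every counting interval too narrow. The deposited table holds cells left after quality control, as its title says. Each gene in it had a count in at least 10 cells, and each cell had counts for at least 7057 genes. No genes encoded by the mitochondrial genome had a row, so the 13 listed mitochondrial mRNAs and the mitochondrial share were not analysed here. RNA editing was not analysed here either, since a count table holds no base calls. Doublets were not called.

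The cells fell into the groups TRIBEID, with 394 cells, and ctrl, with 64 cells, as their titles give them. No cell label names rapamycin, so neither group is described here as treated. All ctrl cells came from row H of their plates and all TRIBEID cells from rows A to G, so group and plate row cannot be told apart. Each cell is a separate sample in the labels and no culture, passage or day is named. Each group was therefore handled as 1 sample, and no test between the groups was made. The 6 plates each held cells of both groups and were used as batches within which each comparison was repeated. The labels do not say whether plates share a culture or a day, so a spread over plates cannot be assigned to technique or to culture.

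Counts were summed over the cells of a group and divided by the group's total to give CPM, the count scaled to a fixed total. The ratio of the groups was log2((CPM in TRIBEID + 1)/(CPM in ctrl + 1)), which understates the ratio of low genes. Exact Poisson intervals at 95% were taken for the sums and cover counting error only. Genes were kept when the mean CPM of the groups was at least 20 and at least 25% of all cells had a count, which left 6779 genes. Genes were counted as higher or lower by size when the pooled ratio was at least 1.5 and all 6 plates had the same direction. The filter, this rule and 28 gene lists were fixed before the data were examined. A list's median ratio was placed among the medians of 10000 random lists matched on mean expression in 20 bins. Random members were drawn singly, so the percentiles leave out that members of a list can vary together between cells. Named genes were LSM14A, ADAR, ADARB1, FKBP1A, MTOR and FKBP5 whatever their values. To these were added the 12 highest and 12 lowest ratios with the same direction in all plates, up to 2 members per list by the size of the ratio, and the 12 most variable genes at 50 CPM or more. A gene that this rule names is not reported here. MYCT2AGFP, ANKRD36B, ANKRD36C, EIF5A and the genes named in the hypothesis on BMP targets were chosen after their values were seen.

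Total counts per cell ran from 143994 to 2040698, which limits the precision of low genes in single cells. For genes per cell and cell cycle scores, each cell was thinned to 367565 counts, which left out 41 TRIBEID and 5 ctrl cells. Scores were means of log2(CPM + 1) over the listed S phase and G2/M genes, centred on the plate. A cell was called G2/M when that score was above 0 and above the S score, S when only the S score qualified, and G1 otherwise. Cell-to-cell variation was taken in TRIBEID cells, within each plate. It was the residual of log10 squared coefficient of variation from a lowess curve on mean expression (fraction 0.3).

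The steps were tested on simulated counts drawn from the real gene means and cell totals, with 200 genes altered. Only the step for ratios also used the real spread of each gene. Among 6826 simulated genes past the filter, the rule of size and direction recovered 94.7% of genes altered 2-fold and 50.0% of those altered 1.5-fold. It also counted 15 of 6633 unaltered genes. Genes were simulated independently, with no plate effect and no state shared between genes, so these rates may not hold for the real cells. In the simulated variation step on 6779 genes, 100% of genes with a 4-fold raised dispersion lay above the curve in all 6 plates, against 1.37% of the others. All the others were given the same dispersion, unlike real genes, so these shares do not carry over to the real cells. Alternatives covered the scaling, the weight of cells, the pseudocount, the filter, the plates and the depth. Subsets of cells by phase or by genes detected, and the alternatives for the S score and the share called G1, were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The TMM factors, used only as an alternative scaling, came from edgeR 4.0.16 in R 4.3.3. Gene coordinates are from GENCODE release 29 on the same build as hg38, in which 23070 of the 24624 gene names were found.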

Results

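Single-cell transcriptomes of 458 HEK293T cells were compared between the groups TRIBEID and ctrl. The series describes cells that carry an LSM14A-TRIBE-ID system, with or without rapamycin. LSM14A is an RNA-binding protein of processing bodies, cytoplasmic granules that hold repressed mRNAs. In TRIBE methods an RNA-binding protein is tied to the catalytic domain of an ADAR enzyme, which edits adenosine to inosine in bound RNAs, and rapamycin can bring separate parts of such a system together through FKBP1A and a domain of MTOR. The labels do not say which cells received rapamycin. Plates 1 to 6 held 70, 61, 66, 76, 60 and 61 TRIBEID cells and 12, 10, 10, 10, 12 and 10 ctrl cells. The summed count was 303446484 in TRIBEID and 48751743 in ctrl, and the median per cell was 732852 and 700882. As each group is 1 sample, the values below describe these cells and have no replicate check. Poisson intervals cover counting error only.

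The first question was whether genes related to such a system differed between the groups. Apart from FKBP5, they were nearly level in the pooled cells. No label gives the sequences of the construct, and endogenous transcripts were not separated from it. These gene rows therefore do not measure the construct alone. LSM14A (chromosome 19, 34172504 to 34229515) stood at 489 CPM in TRIBEID (95% Poisson interval 486 to 491) and 490 CPM in ctrl (484 to 496), and all cells had counts for it. ADARB1 (chromosome 21, 45073853 to 45226560), which encodes an adenosine deaminase, stood at 390 CPM (388 to 393) and 367 CPM (361 to 372). A row named MYCT2AGFP, absent from the annotation used for coordinates, stood at 239 CPM (237 to 241) and 223 CPM (219 to 227). The log2 ratio was 0.01 for FKBP1A, 0.03 for MTOR and -0.03 for ADAR, the gene of another adenosine deaminase. FKBP5, a co-chaperone that binds rapamycin-like drugs, had a ratio of 0.37.

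The plates did not share a direction for these genes. The ratio of ADARB1 was 0.65, 0.62 and 0.81 in plates 1, 2 and 3, but -0.53, -0.06 and -0.39 in plates 4, 5 and 6. LSM14A ran from -0.33 to 0.52 and MTOR from -0.90 to 0.68, each higher in TRIBEID in 3 of 6 plates. FKBP5 was higher in 5 of 6 plates and ran from -0.51 to 2.11. The mean over plates was 0.18 ± 0.58 for ADARB1 and 0.03 ± 0.35 for LSM14A (SD, n = 6 plates). For FKBP5 it was 0.81 ± 1.05, well above the pooled ratio. All these differences lay within the spread between plates.

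ADARB1 and MYCT2AGFP levels went together from cell to cell. Across the 394 TRIBEID cells, centred on their plates, Pearson's r was 0.929 and Spearman's rho 0.920, and r within single plates ran from 0.908 to 0.957. Without the 2 cells farthest from the median of MYCT2AGFP, r was 0.916. The 64 ctrl cells gave r of 0.847, with 0.657 to 0.965 within plates. LSM14A reached 0.406 with MYCT2AGFP, ADAR 0.287, MTOR 0.272 and FKBP1A 0.247 in TRIBEID. Among 9653 genes with counts in at least 50% of cells, the next after ADARB1 was EIF5A, the gene of a translation factor, at 0.601. Cells of a group are not independent cultures, and no p-value was taken from them.

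**Figure D1:**
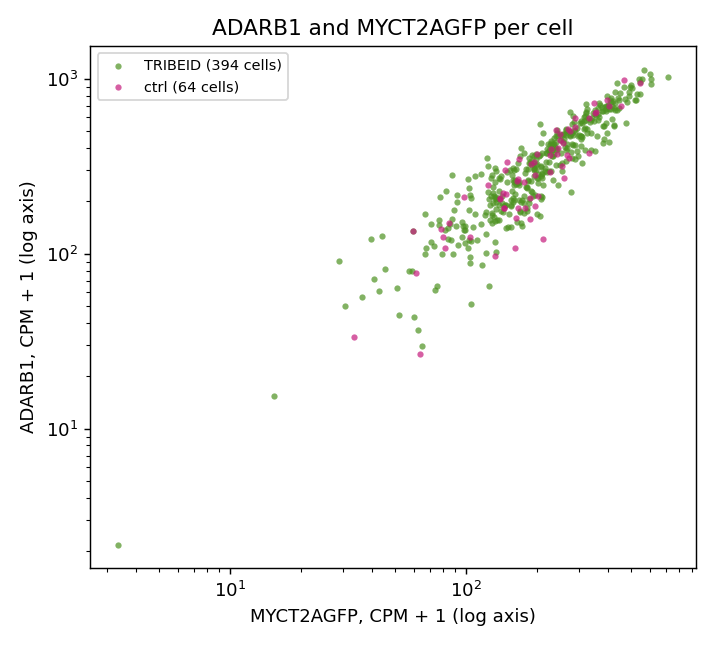
ADARB1 against MYCT2AGFP in each cell, in CPM plus 1 on log axes, for 394 TRIBEID cells and 64 ctrl cells. Both groups lie along the same band, with r of 0.929 in TRIBEID and 0.847 in ctrl after centring on plates.

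The next question was which genes differed between the groups. The transcriptomes were close, with 99.0% of the 6779 genes past the filter within 1.5-fold and r of 0.990 across genes, which are not independent replicates. By the rule of size and direction, 26 genes were higher and 2 were lower in TRIBEID. In simulated data with this number of cells, 15 of 6633 unaltered genes met the same rule. The simulation held no plate effect and no state shared between genes, so its counts are not a background rate for the real genes. In all 6 plates, 196 genes were higher and 83 lower, where coin tosses would give 106 in each direction. Of the 6633 unaltered simulated genes, 124 were higher and 88 lower in all plates. Those genes leaned to higher with no difference built in. A lean to higher among the real genes therefore need not mean a difference between the groups. Scaling by the median ratio turned the split of 196 and 83 to 142 higher and 140 lower, while TMM scaling gave 189 and 82 and the mean over cells 193 and 88.

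Of the 26 higher genes, 4 were members of the G2/M list, as were 3 of the 12 highest. KIFC1 (chromosome 6, 33391536 to 33409924), a kinesin motor of the spindle, stood at 40.3 CPM (39.6 to 41.0) in TRIBEID and 15.6 CPM (14.5 to 16.8) in ctrl, a log2 ratio of 1.31. PLK1, a mitotic kinase, had a ratio of 0.94, and TOP2A, a topoisomerase that untangles chromosomes, stood at 398.8 CPM against 214.8 CPM, a ratio of 0.89. KIF14, a kinesin of cytokinesis, reached 0.86 and HJURP, the chaperone of centromeric histone, 0.84. ID1 (chromosome 20, 31605283 to 31606515), an inhibitor of basic helix-loop-helix transcription factors, stood at 30.1 CPM (29.5 to 30.7) against 12.2 CPM (11.3 to 13.2), a ratio of 1.23. FN1, which encodes the matrix protein fibronectin, reached 0.89. PALM2AKAP2, SNX10, ANKRD36, GATAD1 and BCAS3 completed the 12 highest, with ratios from 0.73 to 0.79. ANKRD36 has near-identical copies, of which ANKRD36B and ANKRD36C were also among the 26, so reads could be split between them.

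The spread over plates was wide for most of these. KIFC1 ran from 0.05 in plate 5 to 2.63 in plate 6, and TOP2A from 0.07 in plate 3 to 1.90 in plate 1. Of the 26 higher genes, 12 met the rule after cells were thinned to the same depth and 2 met it among cells with 8000 to 11000 genes detected, a subset added after seeing the data.

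The lower set held MAN1A1 and SOAT1 past 1.5-fold. MAN1A1 (chromosome 6, 119177209 to 119349761), a mannosidase of the Golgi, stood at 21.4 CPM against 34.3 CPM, a ratio of -0.66. SOAT1, which esterifies cholesterol, stood at 73.5 CPM against 113.8 CPM, a ratio of -0.62. ARHGAP12, AEBP2, CROT, MYEF2, SLC5A3, TRIP4, CCDC32, SULF2, TXNL1 and FKBP7 followed with ratios from -0.57 to -0.41. TXNL1 and SULF2 were the steadiest over plates, at -0.41 ± 0.14 and -0.44 ± 0.20 (SD, n = 6 plates).

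**Figure D2:**
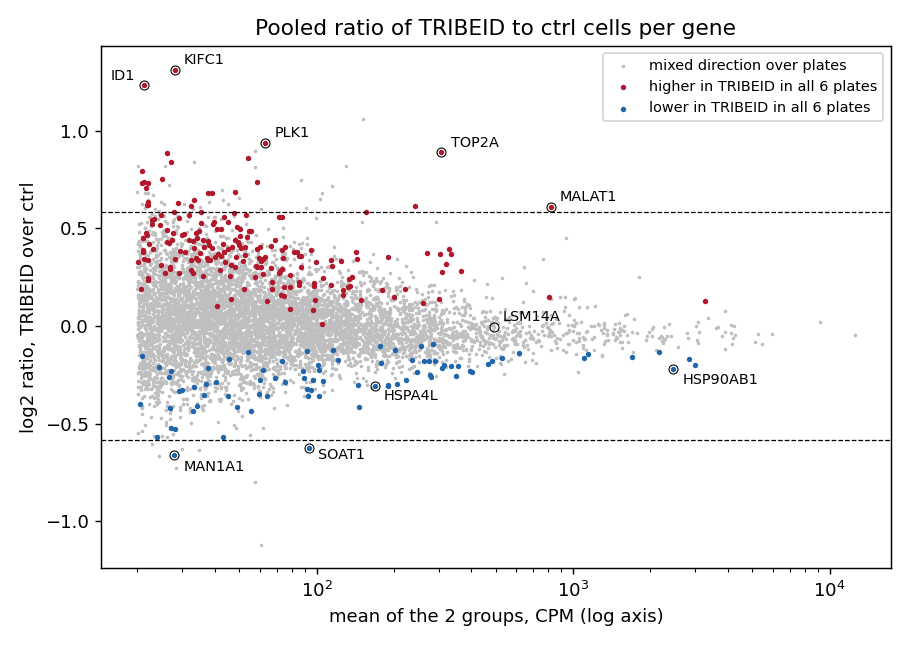
Log2 ratio of TRIBEID to ctrl against mean CPM (log axis) for 6779 genes, pooled over cells. Red and blue mark the 196 genes higher and 83 genes lower in TRIBEID in all 6 plates, and dashed lines mark 1.5-fold. KIFC1 and ID1 stand highest among the marked genes.

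The G2/M genes stood apart as a group. Of 51 members past the filter, 48 had a pooled ratio above 0, 8 were higher in all 6 plates and none was lower in all of them. Their median log2 ratio was 0.34, above all 10000 random lists, whose central 95% ran from -0.05 to 0.04. That range can be too narrow for genes that vary together between cells, given the few ctrl cells. The median was above 0 in 5 of 6 plates, from 0.25 to 0.62, and -0.06 in plate 3. It was 0.19 with cells thinned or with each cell weighted equally, and 0.13 among cells with 8000 to 11000 genes detected. S phase genes had a median of 0.06 over 41 members at percentile 99.4, and their median was above 0 in 4 of 6 plates. Only BRIP1, a DNA helicase, was higher in all plates, at 0.40. Of 7 replication histone genes none had the same direction throughout; H4C3 had a ratio of 1.06 and H1-4 of 0.89, both higher in 5 of 6 plates. Many histone genes are close copies of each other, their counts are uncertain, and only these 7 of the 45 listed passed the filter.

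Scores per cell were compared after thinning. The mean S score was higher in TRIBEID by 0.24, and in each of the 6 plates, by 0.20, 0.32, 0.47, 0.61, 0.0010 and 0.0067 in plates 1 to 6. The mean G2/M score was higher by 0.33 in TRIBEID over all plates, but the difference ran from -0.24 in plate 4 to 0.97 in plate 1. The G2/M minus S score differed by 0.09, with differences between -0.85 and 0.77 in single plates. Without thinning the differences were 0.28 for the S score, 0.33 for the G2/M score and 0.05 for G2/M minus S. Cells called G2/M made up 38.8% of TRIBEID (exact binomial interval 33.7% to 44.1%) and 33.9% of ctrl (22.1% to 47.4%). Cells called G1 made up 13.9% (10.4% to 17.9%) and 25.4% (14.98% to 38.4%), and cells called S 47.3% (42.0% to 52.7%) and 40.7% (28.1% to 54.3%). The pooled intervals overlapped for each phase, which does not show equal shares, and they treat cells as independent draws. Within plates the share called G1 was lower in TRIBEID in all 6, at 14.1%, 10.2%, 17.2%, 10.9%, 16.4% and 15.1% against 25%, 20%, 22.2%, 42.9%, 25% and 22.2%, but these ctrl shares rest on 2 or 3 cells called G1 in each plate. Of 412 scored cells, 26 lay within 0.1 of a boundary of the G2/M call. Cells near the boundary between S and G1, an S score of 0, were not counted.

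Most other lists were centred near 0. The P-body proteins had a median of 0.03 over 39 members, with none in the same direction in all plates. Their widest ratios were 0.37 for TNRC6A, which recruits deadenylases in microRNA silencing, and 0.33 for XRN1, the exonuclease that degrades decapped mRNA. Stress granule proteins had a median of -0.01 over 21 members, among which EIF3A, a translation initiation subunit, was higher in all plates at 0.39. Cytosolic ribosomal proteins stood at -0.04 over 78 members; RPL8 alone was higher in all plates, at 0.13. Other TOP mRNAs, whose translation responds to mTOR, stood at -0.03 over 16 members, with NAP1L1 higher in all plates at 0.15. The mTOR pathway list had a median of 0.05 over 26 members and GRB10, an adaptor phosphorylated by mTOR, was higher in all plates at 0.31. Ribosome biogenesis stood at 0.02 over 35 members, with HEATR1 higher in all plates at 0.19.

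Heat shock proteins included 3 of 19 members lower in all plates and none higher, with a median of -0.05 at percentile 19.1. HSPA4L, a co-chaperone of the HSP110 family, stood at 150.8 CPM against 186.6 CPM, a ratio of -0.31 ± 0.09 (mean over plates and SD, n = 6). HSP90AB1, a cytosolic HSP90, stood at 2272 CPM against 2650 CPM, a ratio of -0.22. Among 18 ER stress genes the median was 0.03, and PDIA6, a disulfide isomerase, was lower in all plates at -0.18. The 9 long noncoding RNAs had a median of 0.03, and MALAT1, a nuclear RNA, was higher in all plates, at 990.7 CPM against 648.9 CPM and a ratio of 0.61.

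Metabolic lists showed few genes in the same direction. Fatty acid synthesis had a median of 0.14 over 10 members at percentile 98.3, but only ELOVL5, a fatty acid elongase, was higher in all plates, at 0.16, and the list median was above 0 in 3 of 6 plates. Cholesterol synthesis stood at 0.00 over 19 members, with INSIG1 at 0.42 and MSMO1 at -0.29 as its widest. Nuclear encoded OXPHOS genes stood at -0.04 over 65 members, with NDUFA3 higher in all plates at 0.09. Glycolysis stood at -0.04 over 16 members, with SLC16A1 at -0.21 and GPI at 0.10. Lysosome and autophagy genes stood at -0.04 over 28 members, with NEU1 at 0.27.

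Stress and signalling lists varied between plates. ATF4 targets, which respond to amino acid shortage, had a median of 0.01 over 28 members, with DDIT4 at -0.41 and SLC7A5 at 0.22. The p53 targets stood at -0.08 over 16 members at percentile 1.56, with SESN1 at -0.40 and CDKN1A at -0.30, and 2 plates had a median above 0. Zinc finger genes stood at -0.01 over 96 members at percentile 1.27, with ZNF275 at -0.57 and ZNF680 at -0.52, but 3 plates had a median above 0. Interferon stimulated genes stood at -0.03 over 7 members, with IFIT5 at -0.20 and IFITM2 at 0.18, but 5 plates had a median above 0. The 3 immediate early genes past the filter had a median of 0.27, with JUN at 0.49 and MYC at -0.30, and 3 plates had a median above 0. No member of these lists had the same direction in all plates.

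The plates fell on opposite sides of 0 for many lists. The ATF4 targets had medians of 0.16, 0.29 and 0.25 in plates 1, 2 and 3 and -0.16, -0.08 and -0.25 in plates 4, 5 and 6. The stress granule list had the same signs, while ribosomal proteins and OXPHOS genes had the opposite ones, at -0.11, -0.17 and -0.15 against 0.10, 0.11 and 0.02 for ribosomal proteins. Plates 1 to 3 and plates 4 to 6 are set apart here only because their values fell so, and no label names this split. Across genes, the plate ratios correlated at 0.24 to 0.28 among plates 1, 2 and 3, at 0.07 to 0.16 among plates 4, 5 and 6, and at -0.12 to -0.02 between them. The median number of genes per cell was 11745, 9250 and 10367 in TRIBEID cells of plates 1, 2 and 3, against 9475, 8290 and 8676.5 in ctrl cells. In plates 4, 5 and 6 it was 10199, 9958 and 9273 against 10250.5, 10352.5 and 9766.5. Over all plates the median was 10056 and 9175.5 genes, and 9522 and 8763 after thinning, but the mean of the within-plate differences after thinning was 376 genes. The median total count, higher in TRIBEID in the pooled cells, differed by -11106.5 as the mean within plates.

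**Figure D3:**
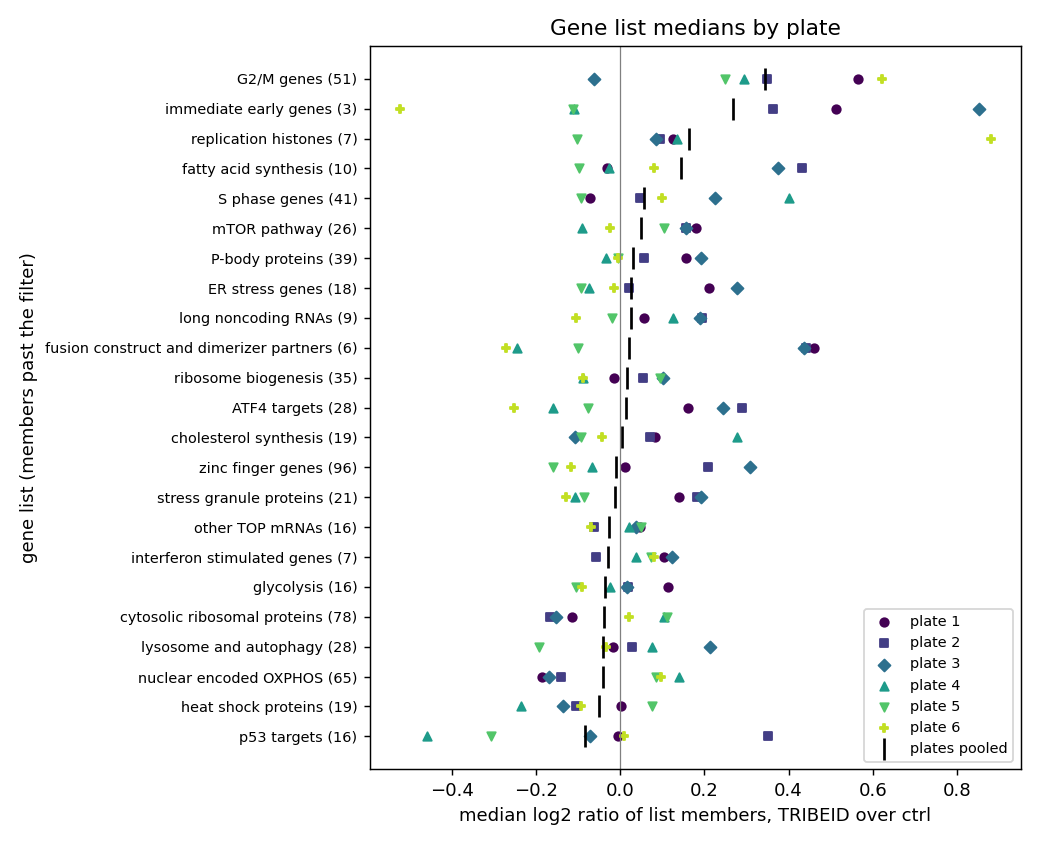
Median log2 ratio of TRIBEID to ctrl for each gene list, with the number of members past the filter. Each symbol is a plate and the black bar is the pooled value. The G2/M list has the highest pooled median, 0.34, and several lists have plates 1 to 3 and plates 4 to 6 on opposite sides of 0.

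Markers of other cell types were checked as well. The keratinocyte list had 3 measured genes, of which KRT10 reached 127.5 CPM in TRIBEID and 133.2 CPM in ctrl, with counts in all cells. The epithelial carcinoma list had 5, with KRT18 highest at 36.5 CPM and 34.2 CPM. None of 8 blood cell markers and 7 fibroblast markers reached 20 CPM in either group, the highest being CORO1A at 3.04 CPM and COL1A1 at 2.65 CPM in TRIBEID.

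The last question was which genes varied most between cells of the same group, taken in TRIBEID cells only. CALCB, which encodes a calcitonin gene-related peptide, led, with a log10 residual of 1.28 ± 0.09 (SD, n = 6 plates) and a coefficient of variation of 2.07. CCNB1, the mitotic cyclin B1, followed at 1.15 ± 0.07, then ID2 at 1.10 ± 0.13 and TOP2A at 1.08 ± 0.22. H4C3, AURKA, UBE2C, PMAIP1, DLGAP5, KPNA2, IRS4 and NEFL completed the 12, between 0.92 and 1.00, and 5 of the 12 were G2/M list members. Of the 51 G2/M genes, 48 lay above the curve in all 6 plates, with a median residual of 0.52. S phase genes had a median of 0.19 and heat shock proteins also 0.19, both above all random lists, as were the zinc finger genes at 0.07. Nuclear encoded OXPHOS genes varied less than each of the random lists, with a median of -0.23. ADARB1 had a residual of 0.45 ± 0.17 and LSM14A of 0.11 ± 0.07.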

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

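Of 107 sets of 6 plate values, 7 held a plate far from the others, where chance alone would give 5.35. The BCAS3 ratio was 1.74 in plate 3 and 0.41 to 0.76 in the other plates. ELOVL5 stood at 0.66 in plate 3 and 0.01 to 0.20 elsewhere. HEATR1 stood at 0.83 in plate 2 and 0.04 to 0.15 elsewhere. INSIG1 stood at 2.32 in plate 2 and -0.20 to 0.74 elsewhere. TRIP4 stood at -1.23 in plate 6 and -0.43 to -0.11 elsewhere. XRN1 stood at -1.19 in plate 4 and 0.46 to 1.05 elsewhere. The median of the replication histones was 0.88 in plate 6 and -0.10 to 0.14 elsewhere. No explanation was tested for these plates.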

How the results depend on the processing

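The subsets by phase and by genes detected, and the alternatives for the S score and the share called G1, were chosen after seeing the data. The difference in G2/M score was 0.18 to 0.42 without a plate, which moves past 1.5 times from 0.33 at the lowest, that in S score 0.19 to 0.30 and that in the share called G1 -12.8 to -8.54 percentage points without a plate. The 24 genes with the highest or lowest ratios kept their direction in all 480 values over 20 alternatives, but they were chosen for one direction in all plates, so the filters, the pseudocounts, the replicate block and leaving out a plate could hardly turn a sign. Of 458 list medians under alternatives, 445 moved by less than the spread between plates. That spread can exceed the median itself, at 0.19 against 0.06 for S phase genes, so the count does not show stability. With TMM scaling the medians turned to -0.02 for S phase genes, -0.04 for P-body proteins and -0.02 for the mTOR pathway. The G2/M list stayed at 0.27 with TMM scaling. Against 26 genes higher and 2 lower, the replicate block (mean of the within-plate ratios) gave 42 and 1, no filter 535 and 9, a filter of 5 CPM and 10% of cells 122 and 5, and one of 50 CPM and 50% of cells 7 and 1; the filters test other numbers of genes. Counts of lower genes were 5 with TMM scaling and with the mean over cells, 1 with capped cells or a pseudocount of 5 CPM, and 9 among cells not called G2/M and among cells with 8000 to 11000 genes. Leaving out each plate gave 36 to 72 higher and 4 to 8 lower, as 5 plates share a direction more often than 6. The higher count moved past 1.5 times without plates 3, 4, 5 and 6, to 55, 53, 72 and 52, and the lower count did so without each plate.

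The interferon list median moved to -0.10 with TMM, 0.055 with no filter, 0.13 with the strict filter, 0.11 with thinned cells, 0.15 among cells with 8000 to 11000 genes and -0.052 to 0.073 without a plate. Other TOP mRNAs moved to -0.10 with TMM, 0.028 among cells not called G2/M and 0.027 among cells with 8000 to 11000 genes. Replication histones moved to 0.89 with the strict filter, and immediate early genes could not be given there or among cells with 8000 to 11000 genes. Without a plate, medians ran from 0.07 to 0.17 for fatty acid synthesis and 0.05 to 0.48 for immediate early genes. For p53 targets they ran from -0.18 to -0.05. The replicate block gave 0.03 for zinc finger genes and 0.03 for interferon stimulated genes, against -0.01 and -0.03 in the pooled cells. The G2/M list moved to 0.085 among cells not called G2/M, which that selection brings about, and its variation to 0.45 in ctrl cells. For the other moves the cause was not tested. The replicate block gave 376 genes for the difference in median genes per cell after thinning, which was 562 to 1068.5 without a plate, -11106.5 for the difference in median total count, which was -19708.5 to 39340 without a plate, and 0.02 for the G2/M minus S score, which was -0.08 to 0.23 without a plate. Alternatives without mitochondrial genes were not run. Depth limits the genes below the filter.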

Other observations

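In this part, the tests on the construct transcript, on fewer genes in ctrl cells and on BMP targets were chosen after the results were seen.

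ADARB1 and MYCT2AGFP went together between cells more closely than MYCT2AGFP and any other gene compared. Differences in genes detected per cell were tested as a cause and excluded by the bound set beforehand: with genes detected and total count held fixed, the partial r was 0.901. Whether a single construct transcript carries both sequences stays open: the r of 0.929 within plates is the observation itself and does not test it. Endogenous ADARB1 was not separated from any construct.

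G2/M genes were higher in TRIBEID, and 2 technical explanations were tested. The first, fewer genes detected in ctrl cells, was tested in the 3 plates where their median number of genes was not lower. The list median there was 0.25 at the lowest. In plate 4, however, the G2/M score was lower in TRIBEID by 0.24. In plates 5 and 6 that score was higher, by 0.37 and 0.38, but only 12 and 9 ctrl cells were scored. The SD over those ctrl cells was 1.18 and 0.97, so these plates cannot exclude this cause. It stays open, and the pooled median was 0.13 among cells with 8000 to 11000 genes. The outer row cannot be told apart from the group: TRIBEID cells of row A had a G2/M score of -0.32 relative to rows B to G, but the SD over 5 plates was 0.64 and 34 cells were scored. Chance make-up of the few ctrl cells and a difference between the groups in rapamycin or in culture stay open and untested.

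The plates disagreed on the direction of many gene ratios, with r across genes down to -0.12 between plates. With cells thinned to the same depth the lowest r was -0.16, which met the bound set beforehand against depth as the cause. Thinning also left out 41 TRIBEID and 5 ctrl cells. The -0.16 thus rests on other cells than the -0.12 and does not by itself exclude depth. After the slope of each gene on genes detected was removed, the lowest r was -0.054. That met the bound set for this cause, though 6 of 15 pairs of plates stayed below 0. The slope was fitted with its own weight in each plate, so removing any related trait could raise r in the same way. The test therefore cannot tell genes detected from other causes. That slope correlated with the ratios at 0.40 to 0.45 in plates 1, 2 and 3 and at -0.17 to -0.10 in the others. In those the mean log2 number of genes differed by -0.02 to 0.04 between the groups, but after thinning the median was lower in TRIBEID in plates 4, 5 and 6, at 9738 against 10516, 9382 against 9695 and 8869 against 9837. Removing a trend on GC content and length gave -0.083, which met the bound set for this cause and the bound set against it, so that test decides nothing. No label ties plates to a treatment or day, so a biological explanation was not tested.

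A hypothesis was that ID1 and ID2, both targets of BMP signalling, may mark a wider difference. Both were higher in all 6 plates, with pooled ratios of 1.23 and 0.62, but not to the same degree in each plate. ID1 stood at 3.02 in plate 1 and 0.56 in plate 5, where ID2 stood at 0.04 and 2.21. In plate 6 both were high, at 2.13 and 2.05. Of 13 further BMP targets listed after several of their values were seen, 4 passed the filter. Their median log2 ratio was 0.28, at percentile 99.1 of random lists, with ID3 at 0.37, ID4 at 0.36, HEY1 at 0.19 and MSX2 at -0.07. None of the 4 was higher in all plates, and they are too few to decide.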
